A study of Homo sapiens with 4 samples.

How the data were processed

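RNA from human primary keratinocytes was measured on 4 Affymetrix HG-U133 Plus 2.0 arrays, 1-colour arrays on which each transcript is read by probe sets of short oligonucleotides. Per the labels' protocols, the cells were grown in a medium that keeps them self-renewing, received a control or a DDX6 short hairpin RNA (shRNA) from a retrovirus, and gave total RNA that was biotin-labelled and hybridised at a core facility. The series design text places the RNA harvest 7 days after knockdown. The labels put 2 arrays in each group and call them biological replicates, but nothing in them says whether these came from separate donors or cultures, so the p-values measure the spread between these arrays, which may be partly technical.

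The deposited values are probe set intensities on a linear scale, as their range and their medians near 50 show (51.2 to 56.3 over the 4 arrays). The probe set summary method, the scaling between arrays and the software the authors used are not given in the sources used here. The distributions of the 4 arrays were close but not identical, so the probe set values as deposited did not share 1 common distribution. This does not tell whether the arrays were normalised before the probe sets were summarised. No count or depth exists for such values. The number of arrays limits the precision, and dim probe sets carry relatively more background.

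The intensities were used without further scaling, as log2(intensity + 16). A fold change below is on that scale, which understates the change of dim genes. The deposited table holds 54675 probe sets, of which 62 were array controls. Symbols came from the array's annotation table and were checked against a RefSeq gene table through gene IDs. A single symbol was assigned to 41091 probe sets. Of these, 41037 matched by gene ID with no symbol changed, and 54 kept the array's symbol. The 1801 probe sets with several symbols and the 11721 with none were not named. Of the single-symbol probe sets, 59 that read Y chromosome genes or X inactivation transcripts were left out, while other X-linked genes stayed in. Probe sets in the upper 60% by mean over all arrays were kept (32768 probe sets, mean intensity above about 36.0), and each gene was then represented by its probe set with the highest mean, which left 14600 genes. Among 2873 genes called changed that had more than 1 probe set, 83 had another probe set called in the opposite direction.

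DDX6 shRNA arrays were compared with control shRNA arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, 2-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Each gene had 2 residual degrees of freedom, and the empirical Bayes prior added 3.01. A total of 22 gene lists, 19 of pathways and 3 of markers of other cell types, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. The correlation was also estimated from the data, which rests on the same 2 residual degrees of freedom. Each list was also tested by fry, which asks whether its genes changed, where camera asks whether they differ from the other genes. None of the 8 lists called with the preset correlation was called with the estimated correlation, whose adjusted p is printed beside each. With the correlation estimated, camera takes its p-value from a distribution with 2 residual degrees of freedom, which makes any call unlikely. The cholesterol list lost its call although its estimated correlation, -0.000178, was below the preset 0.01. Such a lost call therefore does not by itself show that correlation between genes explains a result. Among the called lists the estimate was highest for differentiation transcription factors (0.502) and for cell cycle inhibitors and p53 targets (0.257). For these lists correlation may also have contributed to the lost call. Counts of list members are given over all genes tested and adjusted over the list alone.

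The groups, tests, lists and naming rule were fixed before the data were examined. Named genes were DDX6 with all its probe sets, and the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap. From each list up to 2 rises and 2 falls past the threshold were named, or, where none passed, the 2 members with the lowest unadjusted p. KLF4, EDC3, EIF4E, YBX1, CDK1 and EZH2, which the study is remembered to have followed, completed the set. Any other gene named was chosen after its values were seen, which is said beside it or at the head of its part.

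The fit was tested on simulated data for this comparison of 2 against 2 arrays over 14600 genes. It recovered 1 of 50 genes changed 1.2-fold, 24 of 50 changed 1.5-fold, 46 of 50 changed 2-fold and 50 of 50 changed 4-fold. It called 5 of 14400 unchanged genes. Only 200 genes were simulated as changed, and the noise was normal, independent between genes and drawn from the fitted prior. In the data 5455 genes were called, so the adjustment is less strict there and these rates do not carry over. The alternatives tried were other filters on dim probe sets, quantile, median and cyclic loess scaling, another log offset, other ways to represent a gene, a trended or robust variance model, a replicate block, other thresholds and leaving out each array in turn. Scaling to the poly-A spike-in control probe sets, an offset of 1 on the probe sets already chosen and a test of gene families were added after the data were seen.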

Results

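The data consisted of 4 expression arrays of primary human keratinocytes, the main cell type of the epidermis, 2 from cells that received a control shRNA and 2 from cells that received an shRNA against DDX6. DDX6 is a DEAD-box RNA helicase of the cytoplasmic mRNA granules called P-bodies, where it takes part in mRNA decapping and translational repression. The comparison asks which transcripts differ 7 days after DDX6 is depleted from cells kept in a self-renewing medium. No rescue group or other DDX6 hairpin is named among the samples, so effects of DDX6 loss cannot be separated from other effects of the hairpin. Direct and later effects cannot be separated at this single time either. Median probe set intensities were 51.2 and 54.7 on the control arrays and 55.5 and 56.3 on the DDX6 shRNA arrays. Log2 intensities correlated across probe sets at r = 0.9947 between the control arrays and 0.9938 between the DDX6 shRNA arrays, against 0.9826 to 0.9852 between groups, where probe sets are not independent replicates. The median absolute log2 difference per gene was 0.082 and 0.073 within the groups and 0.19 to 0.23 between them.

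DDX6 itself was reduced on both DDX6 shRNA arrays. Its brightest probe set read 2788 ± 35.0 (SD, n = 2) in control cells and 284.7 ± 1.19 (SD, n = 2) after knockdown, 10.2% of control, with a log2 fold change of -3.22 (SE 0.06, limma adjusted p = 0.000181). The 2 dimmer probe sets fell to 16.2% and 17.4% of control. The array labels therefore matched the targeted transcript on all 4 arrays.

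**Figure D1:**
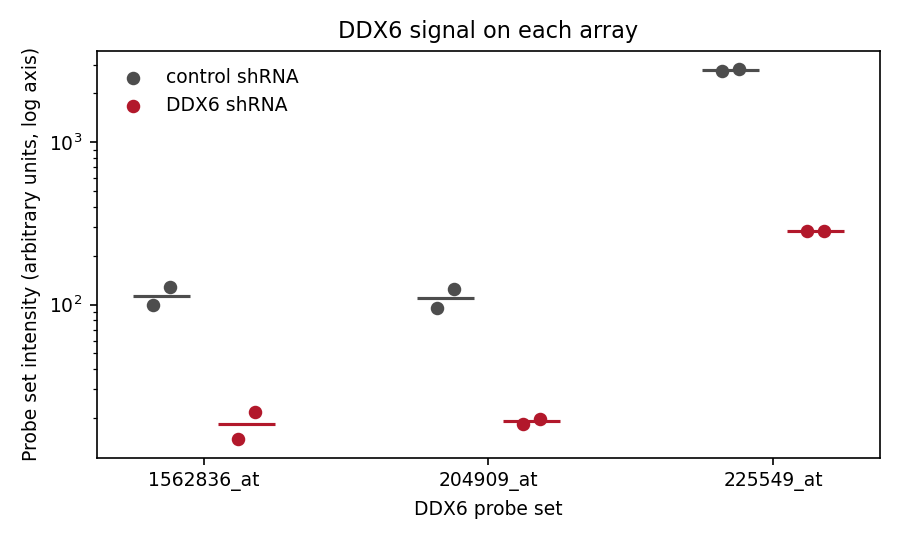
Intensity of the 3 DDX6 probe sets on each array, in arbitrary units on a log axis, with points for single arrays and lines for the mean of 2 arrays. Both DDX6 shRNA arrays lie below both control arrays for every probe set, and the brightest falls from a mean of 2788 to 284.7.

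The expression of 5455 of 14600 genes (37.4%) differed between the groups at an adjusted p under 0.05, 2908 higher and 2547 lower after DDX6 knockdown. At least a 2-fold difference was found for 507 genes, 202 higher and 305 lower. The arrays of the 2 groups did not overlap for any of the 5455 genes, nor for 70.8% of all genes tested, where chance gives 33.3% for 2 against 2 arrays. The split by direction depended on the scaling between arrays. Of the changed genes 53.3% were higher with the deposited scaling, against 42.1% after median centring (2425 higher, 3336 lower) and 90.6% after scaling to spike-in probe sets (9008 higher, 937 lower), which moved the median of all genes by 0.29 on the log2 scale. The count fell to 3302 without control array 1, 4144 without control array 2, 3294 without DDX6 shRNA array 1 and 2644 without DDX6 shRNA array 2, while 500 to 532 genes differed at least 2-fold.

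Among the 10 largest rises were products of surface and suprabasal epithelia. The kallikrein protease KLK7, which acts in the shedding of corneocytes, rose 5.99-fold (log2 fold change 2.58, SE 0.06, adjusted p = 0.000181) from 252 ± 12.6 to 1590 ± 23.0 (SD, n = 2 each). SPINK6, an inhibitor of kallikreins, rose by 3.36 on the log2 scale, KRT13, a keratin of mucosal suprabasal cells, by 3.30, and UPK1B, a uroplakin of the urothelium, by 2.58. CALB1, a calcium-binding protein, had the largest rise, 3.59 (SE 0.24), from an intensity of 24.3 ± 14.3 to 454 ± 10.5. Its rise was 4.30 with an offset of 1, and its control mean lay below the filter's 36.0. With an array left out, CALB1 rose by 3.22 to 3.96 and SPINK6 by 3.24 to 3.48, so this rank is not settled. BMP6, a growth factor of the BMP family, rose by 2.62, the cytochrome CYP1B1 by 2.60, the stress-induced transcription regulator NUPR1 by 2.40, PHACTR3 by 2.66 and the non-coding RNA LINC00520 by 2.56. In control cells KRT13 was also dim, at 36.6 ± 25.3.

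After DDX6 itself the largest falls were GPX2, a glutathione peroxidase, at -3.13 (SE 0.39), and ESM1, a secreted proteoglycan, at -3.11 (SE 0.07). GPX2 stood at -2.52 without DDX6 shRNA array 1 and -3.74 without DDX6 shRNA array 2, and at -3.90 with a log offset of 1, where ESM1 stood at -3.71. The interleukin 7 receptor gene IL7R fell from 135 ± 23.8 to 6.40 ± 3.42 (log2 fold change -2.75). With an offset of 1 on the same probe sets IL7R stood at -4.27, so the order of the largest falls depended on the offset. After knockdown IL7R, GPX2 and ESM1 had mean intensities below the filter's 36.0, so the size of these falls is not well determined. The other 6 serve the cell cycle or the nucleus. RRM2, a subunit of ribonucleotide reductase, fell from 2738 ± 127 to 382 ± 13.4 (log2 fold change -2.79, SE 0.07, adjusted p = 0.000181). CDC20, an activator of the anaphase-promoting complex, had -2.45, the lamin gene LMNB1 -2.40, the centromere histone chaperone HJURP -2.35, DTL, which targets the licensing factor CDT1 for degradation, -2.28, and the kinetochore protein NUF2 -2.28.

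**Figure D2:**
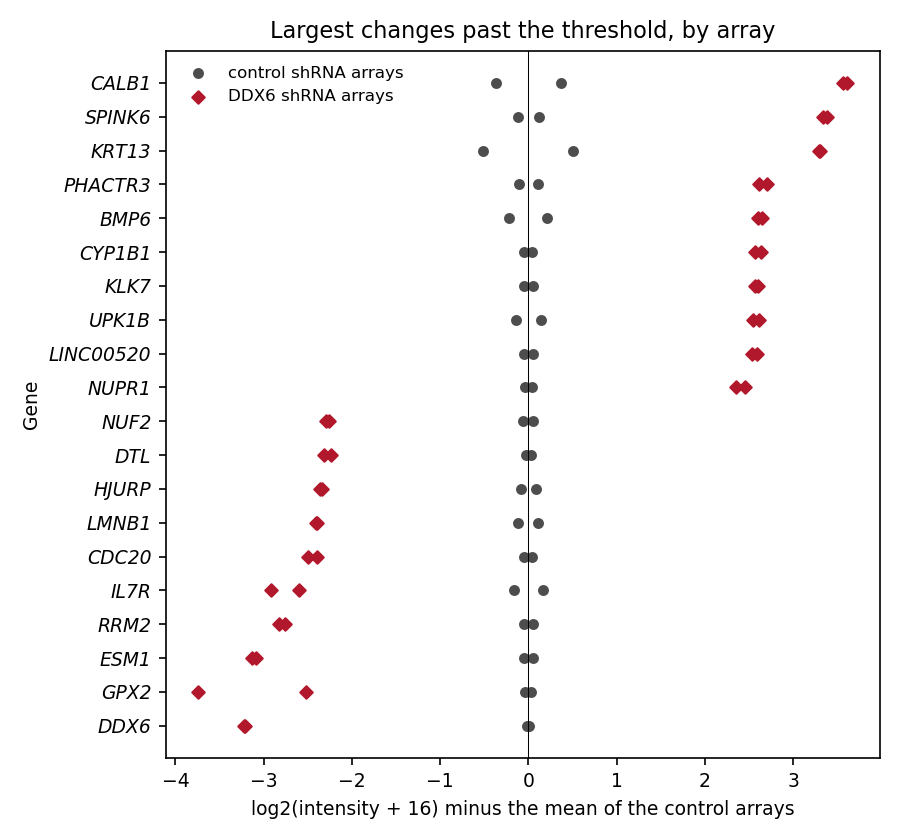
The 10 largest rises and the 10 largest falls past the threshold, as log2(intensity + 16) on each array minus the mean of the control arrays, with circles for control and diamonds for DDX6 shRNA arrays. The DDX6 shRNA arrays lie within 0.2 of each other for most genes, and those for GPX2 lie widest apart.

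Genes of the cell cycle fell almost as a block. Of 39 genes of DNA replication and G1/S, 35 fell (37 adjusted over the list alone), none rose and 4 did not pass, 29 of the falls at least 2-fold, with a list median of -1.27 on the log2 scale. RRM2 and the replication initiation factor MCM10 (-2.23, SE 0.07) had the largest falls. Of 37 genes of mitosis and G2/M, 35 fell (35 adjusted over the list alone), none rose and 2 did not pass, 34 of the falls at least 2-fold, with a median of -1.88, led by CDC20 and NUF2. CDK1, the kinase that drives entry into mitosis, fell from 1994 ± 77.1 to 527 ± 25.1 (log2 fold change -1.89, SE 0.07, adjusted p = 0.000201). Both lists lay below the other genes by camera (adjusted p = 1.49e-22 for replication and 7.2e-27 for mitosis). With an estimated correlation neither was called (adjusted p = 0.212 for replication and 0.20 for mitosis).

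Cell cycle inhibitors and p53 targets moved mostly the other way. Of 28 genes, 14 rose and 2 fell, 12 not passing (15 and 2 adjusted over the list alone), with a median of 0.28. SESN2, a stress-induced regulator of growth signalling, rose by 1.64 (SE 0.08) and the cyclin-dependent kinase inhibitor CDKN1C by 1.51 (SE 0.09), while DDB2, a DNA damage recognition factor, fell by 0.43 and the kinase PLK2 by 0.32. The list lay above the other genes (camera adjusted p = 0.00856; adjusted p = 0.802 with an estimated correlation). The call of PLK2 was lost without control array 1 (adjusted p = 0.0645) and without DDX6 shRNA array 2 (adjusted p = 0.0852).

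Of 14 chromatin regulators associated with progenitor cells, 6 fell and none rose, 8 not passing (6 and none adjusted over the list alone), with a median of -0.19. UHRF1, which maintains DNA methylation at replication, fell by 1.48 (SE 0.06), and EZH2, the histone methyltransferase of Polycomb complex PRC2, fell from 462 ± 6.01 to 260 ± 20.6 (log2 fold change -0.79, SE 0.07, adjusted p = 0.00211). The list was called by camera (adjusted p = 0.0102; adjusted p = 0.348 with an estimated correlation). The call was lost without probe sets marked as matching several transcripts (adjusted p = 0.287). Scaling to spike-in probe sets turned its median to 0.098, where that of all genes was 0.32. Camera called the list there too (adjusted p = 0.00675), but this scaling moves all genes alike, so that is no test of the call.

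Many, but not all, genes of keratinocyte differentiation rose. Of 31 genes of the cornified envelope and terminal differentiation, 19 rose and 1 fell, 11 not passing (19 and 1 adjusted over the list alone), 9 of the rises at least 2-fold, with a median of 0.44. IVL, which encodes involucrin, a scaffold protein of the envelope, rose 4.70-fold from 139 ± 3.31 to 709 ± 6.03 (log2 fold change 2.23, SE 0.06, adjusted p = 0.000181), behind KLK7 in the list. KRT10 (0.059, limma adjusted p = 0.575) and LORICRIN (0.39, adjusted p = 0.419), chosen after their values were seen, did not pass. Only 31 of the 50 genes on the list could be tested. SPRR2B was the gene that fell (-0.38), and it is read by a probe set that can match near-identical SPRR2 genes. Its call was lost without control array 1, control array 2 or DDX6 shRNA array 2 (adjusted p = 0.0649, 0.0738 and 0.0824). The list lay above the other genes (camera adjusted p = 1.07e-06; adjusted p = 0.20 with an estimated correlation).

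Of 16 transcription factors of differentiation, 9 rose and 1 fell, 6 not passing (9 and 1 adjusted over the list alone), with a median of 0.49 (camera adjusted p = 0.00298; adjusted p = 0.802 with an estimated correlation). KLF4, a zinc finger factor needed for the epidermal barrier, rose 3.91-fold from 895 ± 77.4 to 3535 ± 8.04 (log2 fold change 1.97, SE 0.08, adjusted p = 0.000232). GRHL3, a grainyhead-like factor of the barrier, rose by 1.66 (SE 0.09). PRDM1 had -0.32, and its call was lost when any of the 4 arrays was left out (adjusted p = 0.0523 to 0.0898). The mean of the PRDM1 probe sets gave -0.015 (adjusted p = 0.886), and its 2 dimmer probe sets, at 0.14 each, did not pass.

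Other epidermal lists were not called by camera, and fry called that of stress keratins (adjusted p = 0.00812). Of 13 genes of the epidermal lipid barrier, 6 rose and 3 fell, 4 not passing (6 and 4 adjusted over the list alone; camera adjusted p = 0.619), with the sulfotransferase SULT2B1 at 0.77 and the steroid sulfatase STS at 0.50 against the glucosylceramide synthase UGCG at -0.79 and the fatty acid elongase ELOVL4 at -0.75. The call of STS was lost without DDX6 shRNA array 1 (0.50) or array 2 (0.49). Its dimmer probe set had 0.056 and did not pass (limma adjusted p = 0.698 over all probe sets). Of 18 basal keratinocyte and hemidesmosome genes, 6 rose and none fell, 12 not passing (6 and none adjusted over the list alone; camera adjusted p = 0.468), led by the basal keratin KRT15 (0.94, SE 0.06) and the hemidesmosome linker PLEC (0.60). Of 10 stress keratin and antimicrobial genes, 4 rose and 3 fell, 3 not passing (4 and 3 adjusted over the list alone; camera adjusted p = 0.468). The hyperproliferation-associated keratin KRT16 rose by 1.96 (SE 0.06) and the siderophore-binding protein LCN2 by 1.54, whereas the calgranulin S100A9 fell by 0.52 and the elastase inhibitor PI3 by 0.51.

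Inflammatory genes were lower. Of 23 cytokines and NF-kB targets, 13 fell and 1 rose, 9 not passing (15 and 2 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 5.12e-05; adjusted p = 0.217 with an estimated correlation). The neutrophil chemokines CXCL8 and CXCL1 had log2 fold changes of -2.05 (SE 0.11) and -1.79 (SE 0.06), CXCL1 falling from 2630 ± 14.3 to 751 ± 9.09. The gene that rose was IL1RN, the interleukin 1 receptor antagonist, at 1.02 (SE 0.06). Of 38 interferon response genes, 13 rose and 9 fell, 16 not passing (14 and 10 adjusted over the list alone; camera adjusted p = 0.47). IFIT2 and RSAD2, both antiviral effectors, rose by 1.21 and 1.19, while OAS3, a sensor of double-stranded RNA, fell by 0.63 and USP18, which removes ISG15 from proteins, by 0.57.

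Cholesterol synthesis genes fell. Of 17 genes, 14 fell and none rose, 3 not passing (15 and none adjusted over the list alone), with a median of -0.52 (camera adjusted p = 1.88e-07; adjusted p = 0.20 with an estimated correlation). The sterol carrier STARD4 fell by 1.05 (SE 0.07) and the synthase HMGCS1 by 0.98 (SE 0.08). Of 26 genes of the unfolded protein and amino acid stress response, 14 rose and 7 fell, 5 not passing (14 and 7 adjusted over the list alone; camera adjusted p = 0.47). The glutathione-degrading enzyme CHAC1 and the stress transcription factor DDIT3 rose by 1.69 (SE 0.07) and 1.52 (SE 0.07). The endoplasmic reticulum chaperone HSP90B1 fell from 5492 ± 82.0 to 1665 ± 4.19 (log2 fold change -1.71, SE 0.06), and the disulfide isomerase PDIA4 fell by 1.46 (SE 0.06).

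The machinery DDX6 works with showed small changes in both directions. Of 19 decapping and P-body genes, 4 rose and 7 fell, 8 not passing (5 and 8 adjusted over the list alone; camera adjusted p = 0.47). LSM6 and LSM2, subunits of the Sm-like ring that activates decapping, fell by 0.71 (SE 0.07) and 0.59 (SE 0.09). EIF4ENIF1, a partner of DDX6 that binds eIF4E, had 0.32 and LSM14B 0.29. Other LSM14B probe sets had 0.46, 0.15 and -0.063 and did not pass (limma adjusted p = 0.053, 0.228 and 0.534 over all probe sets). The call of EIF4ENIF1 was lost without control array 1, control array 2 or DDX6 shRNA array 2 (adjusted p = 0.0743, 0.0565 and 0.0963), and that of LSM14B without control array 1, DDX6 shRNA array 1 or array 2 (adjusted p = 0.0921, 0.105 and 0.0681).

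Of 29 genes of deadenylation and microRNA-mediated decay, 7 rose and 3 fell, 19 not passing (6 and 2 adjusted over the list alone; camera adjusted p = 0.47), with the Argonaute genes AGO4 at 0.57 and AGO2 at -0.52. The dimmer AGO4 probe sets had 0.38 and 0.10 and did not pass (limma adjusted p = 0.155 and 0.341 over all probe sets). BTG1, an activator of deadenylation, had 0.72 by the probe set used and 0.97 by another bright probe set (adjusted p = 0.00212 over all probe sets). Its dim probe set, the one that remained when those matching several transcripts were left out, had -0.052 (adjusted p = 0.71). CNOT10, a subunit of the CCR4-NOT deadenylase, had -0.31, a call lost without control array 1, control array 2 or DDX6 shRNA array 2 (adjusted p = 0.0695, 0.116 and 0.143).

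Of 38 translation factors, 1 rose and 7 fell, 30 not passing (1 and 3 adjusted over the list alone; camera adjusted p = 0.468). EIF4EBP2, a repressor of eIF4E, had 0.39, EIF5 had -0.42 and EIF2B3 -0.42. The dimmer EIF4EBP2 probe sets had 0.15 and 0.17 and did not pass (limma adjusted p = 0.304 and 0.117 over all probe sets). The calls of EIF4EBP2 and EIF2B3 were lost without DDX6 shRNA array 1 (adjusted p = 0.0561 and 0.0685) or array 2 (adjusted p = 0.0682 and 0.0749), and EIF5 had -0.11 (adjusted p = 0.442) by a dim probe set when those that match several transcripts were left out. The 3 other bright EIF5 probe sets were lower, at -0.71, -0.70 and -0.36. None of 37 cytosolic ribosomal protein genes passed the threshold in limma, over all genes or over the list alone, with a median of -0.011 and a camera adjusted p of 0.591. Their median control intensity of 10970 lay near the array maxima of 16350 to 17730, where signals may saturate and changes may go unseen. RPL3 (-0.10, unadjusted p = 0.203 in limma's moderated test) and RPS27 (0.079) had the lowest unadjusted p.

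Of the genes the study is remembered to have followed, KLF4, CDK1 and EZH2 are given above. EIF4E, the cap-binding protein, read 3385 ± 218 in control and 2571 ± 342 in DDX6 shRNA cells (log2 fold change -0.40, SE 0.11, adjusted p = 0.0425). The call of EIF4E was lost without control array 1, control array 2 or DDX6 shRNA array 2 (adjusted p = 0.153, 0.0726 and 0.133). EDC3, an enhancer of decapping, did not pass the threshold (0.11, adjusted p = 0.253) by its brighter probe set, while its dimmer probe set had -0.37 (adjusted p = 0.0218 over all probe sets). YBX1, an RNA-binding protein, did not pass either (-0.081, adjusted p = 0.311).

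Of 24 immediate-early and short-lived transcripts, 6 rose and 4 fell, 14 not passing (6 and 4 adjusted over the list alone; camera adjusted p = 0.913), with a median of 0.011 and a test directed downwards. The phosphatase gene DUSP1 rose by 1.04 and EGR3 by 0.89, while CCN1 fell by 0.77 and IER3 by 0.73. Of 13 genes of epithelial-mesenchymal transition, 3 rose and 5 fell, 5 not passing (4 and 5 adjusted over the list alone; camera adjusted p = 0.716), and the median was 0.070 with a mean of -0.014 and a test directed downwards. The matrix metalloproteinase genes MMP2 and MMP10 rose by 0.87 and 0.55, and the matrix protein gene TNC and the urokinase receptor gene PLAUR fell by 0.73 and 0.59.

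Lists of markers of other cell types were not called by camera, and fry called the immune and Langerhans cell list (adjusted p = 0.00542). Of 12 dermal fibroblast markers, 5 rose and 1 fell, 6 not passing (5 and 1 adjusted over the list alone; camera adjusted p = 0.473). POSTN had 1.19 and FBN1 1.08, whereas TWIST2 fell by 0.50. POSTN had 0.19 (adjusted p = 0.152) without probe sets that match several transcripts. The collagen genes COL1A1 (-0.15), COL1A2 (0.022) and COL3A1 (-0.0020), abundant in fibroblasts and chosen after their values were seen, did not pass by their brightest probe sets, although 2 of the other COL1A1 probe sets were called higher. Of 8 melanocyte markers, 1 rose and 1 fell, 6 not passing (1 and 1 adjusted over the list alone; camera adjusted p = 0.619), MLPH at 0.67 and OCA2 at -0.32. The call of OCA2 was lost without control array 2, DDX6 shRNA array 1 or array 2 (adjusted p = 0.0619, 0.0785 and 0.0731). Of 9 immune and Langerhans cell markers, none rose and 2 fell, 7 not passing. Adjusted over the list alone, none rose and 2 fell, and the camera adjusted p was 0.47. CORO1A had -1.04 and LAPTM5 -0.55. The call of LAPTM5 was lost without control array 1 (-0.48) or DDX6 shRNA array 2 (-0.40). Its dimmer probe set had -0.059 and did not pass (limma adjusted p = 0.694 over all probe sets).

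**Figure D3:**
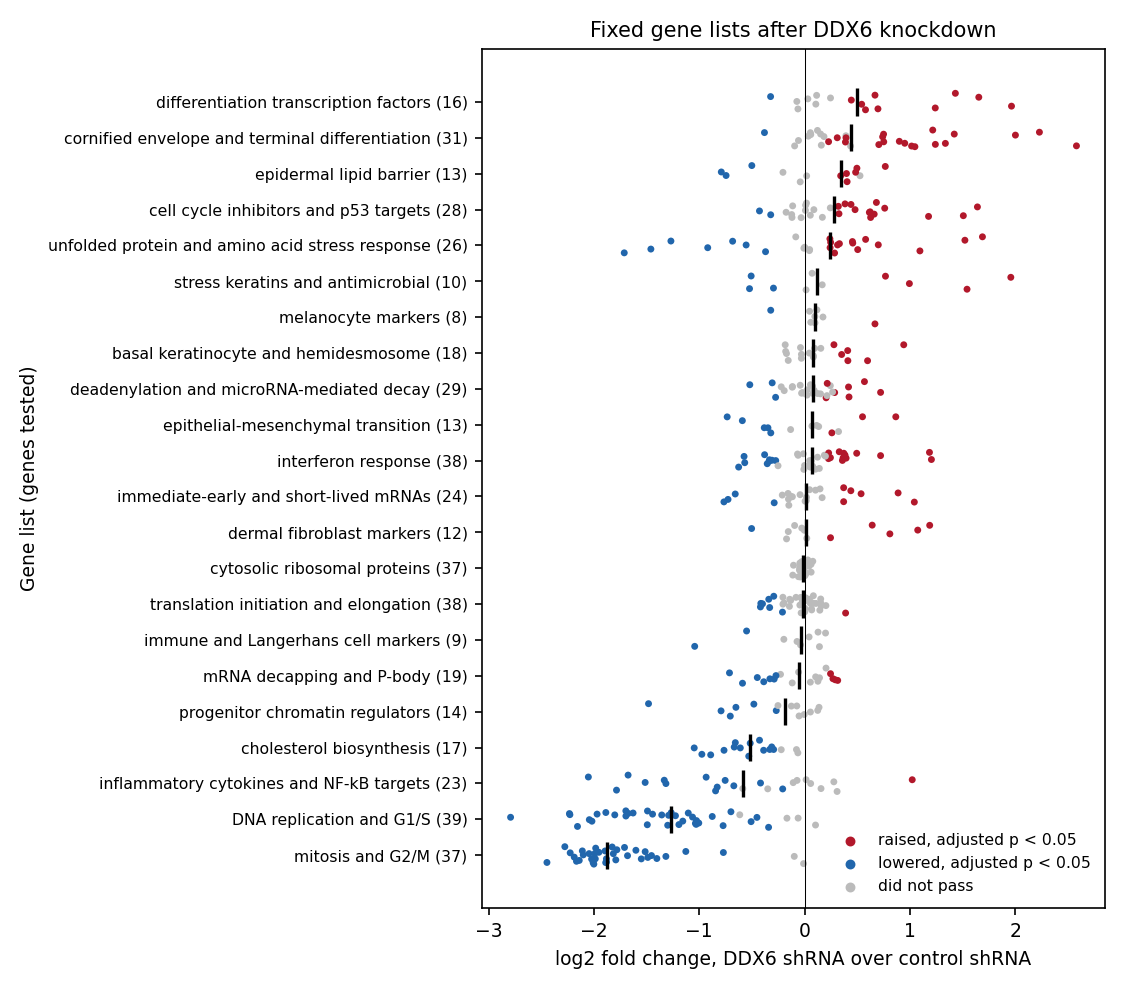
Log2 fold change, DDX6 shRNA over control shRNA, of each tested member of the 22 gene lists, with the number tested in parentheses, coloured points past an adjusted p of 0.05 and black bars at the list median. The lists of mitosis and of DNA replication lie lowest, with medians of -1.88 and -1.27, and differentiation transcription factors highest, with 0.49. Scaling to spike-in probe sets, which moves all genes by 0.29, turns the median of progenitor chromatin regulators from -0.19 to 0.098.

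The control probe sets of the array were also compared, because they read RNA quality and labelling. The ratio of 3' to 5' signal of actin was 1.29 and 1.36 in control and 1.42 and 1.45 in DDX6 shRNA samples, and that of GAPDH was 0.941 and 0.981 against 0.955 and 1.01. The 9 hybridisation control probe sets differed by a median of -0.017 on the log2 scale, while all 12 poly-A spike-in probe sets were lower on the DDX6 shRNA arrays, by a mean of -0.29 (SD 0.081 over probe sets), and all 5 ribosomal RNA probe sets were higher, by 0.61 (SD 0.16). All 6 actin and GAPDH probe sets were lower, by a mean of -0.13 (SD 0.047). No labelling batch could be separated from the groups with 2 arrays in each.

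**Figure D4:**
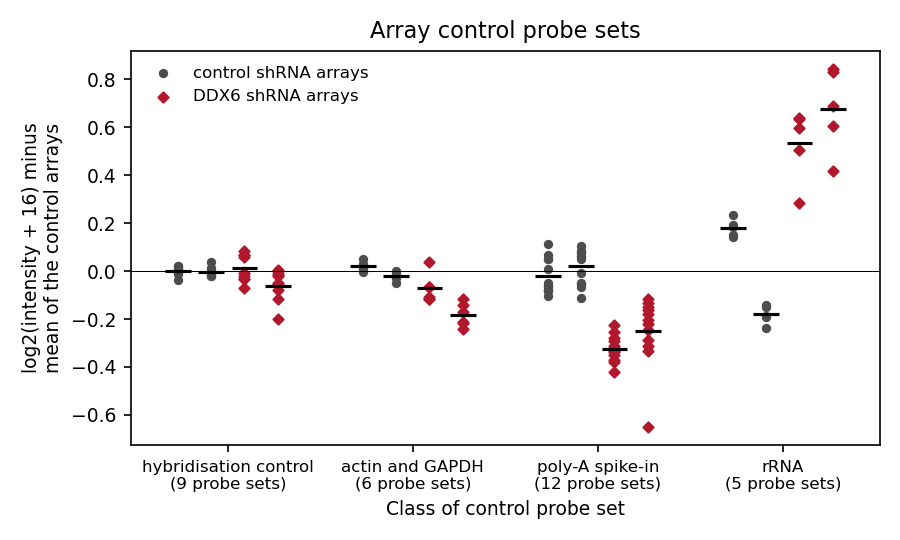
Control probe sets of 4 classes on each array, as log2(intensity + 16) minus the mean of the control arrays, with points for probe sets and bars for their mean on that array. The poly-A spike-in probe sets lie lower on both DDX6 shRNA arrays and the ribosomal RNA probe sets higher, the actin and GAPDH probe sets slightly lower, while the hybridisation controls stay near 0.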

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

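All the tests of explanations in this part were chosen after the results were seen.

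The 5 ribosomal RNA control probe sets, which belong to no gene comparison, were brighter on the DDX6 shRNA arrays by a mean of 0.605 on the log2 scale, and the 12 poly-A spike-in probe sets were dimmer by a mean of -0.29. A difference in hybridisation or scanning would have dimmed the hybridisation controls too, and their median difference of -0.0168 argues against it. The means of the spike-in species moved by nearly 1 common amount, ranging over 0.0805. Less spike-in RNA per sample would give this, but more poly(A) RNA in the sample would give it as well, so these cannot be told apart. Probe sets within the species dap differed by more, 0.293, from -0.501 for its 5' to -0.209 for its 3' probe set. The other species had ranges of 0.0807 to 0.109. The cause of the spread within dap was not tested. More poly(A) RNA per total RNA should have lowered the ribosomal RNA signal; this rise was first read as excluding that, a reading withdrawn because the priming of ribosomal RNA may vary by itself and hide a fall, so it stays open, as does an effect of the knockdown. The 2 control arrays also differed from each other, with mean log2 ribosomal RNA signals of 12.5 and 12.1 against 12.8 and 13.0.

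Among 4555 probe sets with no gene symbol that passed the intensity filter, 800 (17.6%) passed the threshold in a fit of all probe sets. Of the 800, 490 were higher and 310 lower, and 44 changed at least 2-fold. Among 1253 probe sets with several symbols, 357 (28.5%) passed it, 184 higher and 173 lower, 37 of them at least 2-fold. These shares lay below the 37.4% of genes called in the gene comparison, which used each gene's brightest probe set. The counts therefore do not single out these probe sets.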

How the results depend on the processing

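The fall of DDX6 was called under each alternative run, from -3.29 to -2.32, and from -3.23 to -3.21 when an array was left out. For the main results, 100 comparisons with an alternative stayed on the same side and within 1.5 times, and 17 did not. Leaving out an array gave 2644 to 4144 genes changed, 1336 to 2482 raised and 1308 to 1756 lowered, against 5455, 2908 and 2547, and 500 to 532 genes changed at least 2-fold and 8 lists in each case. The fits on 3 arrays assume that the lone array varies like the other group, and fewer samples lower their counts. A threshold of 0.01 gave 2416 genes, 1166 raised and 1250 lowered, by construction. Testing each probe set by itself gave 9027 probe sets, a count of a more numerous unit. Scaling to the poly-A spike-in probe sets, chosen after seeing the data, gave 9945 genes, 9008 raised and 937 lowered, because it shifts the median of all genes by 0.29. It turned YBX1 to 0.21 (adjusted p = 0.0473) and the median of the progenitor chromatin list to 0.098, signs set by that shift. The list stayed below the median of all genes, then 0.32. Camera, which compares it with other genes, called it (adjusted p = 0.00675), which a shift common to all genes can hardly alter. Without probe sets marked _x_at and _s_at BTG1 had -0.052, read by another probe set. Camera with the correlation estimated, on 2 residual degrees of freedom, called 0 lists, where camera with the preset correlation called 8. By fry, which asks a different question, 10 were called, with stress keratins and immune markers added. Unadjusted, 7025 genes had p under 0.05. For named genes 1530 comparisons were unchanged in call and direction, 69 lost the call, 2 gained it and 2 reversed, and for lists these were 447, 10, 2 and 1. The same replicate number did not establish pairing, since the deviations of same-numbered arrays correlated at 0.14 over a single pairing. A replicate block gave 5927 genes changed, 5290 of them shared. An offset of 1 on the same probe sets, also chosen after seeing the data, gave 5077 genes changed and took IL7R from -2.75 to -4.27, since the offset of 16 compresses the folds of dim genes.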

Other observations

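All the tests in this part, the gene families themselves and the genes first named here were chosen after the data were seen. A family was taken as the genes whose symbols share the letters before the first digit, with histones joined into 1, and camera was run on the 230 families of at least 8 genes. The rule was revised once after its first result, to leave out symbols with a hyphen or further parts, which removed most antisense and divergent transcripts but not all. The first version called 17 of 245 families, 4 up and 13 down, and the revised version called these 17 among its 21, 5 up and 16 down. None was called with an estimated correlation (adjusted p = 0.957).

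Several families of genes that the fixed lists did not cover were lower. Of 22 genes with NUP symbols, most of them nucleoporins, 17 fell and none rose, with a median of -0.39 (adjusted p = 1.63e-06) that stayed negative at -0.11 under spike-in scaling. NUP88 fell by 0.88 and NUP37 by 0.68. Of 10 UTP genes, of small subunit ribosome processing, 9 fell and none rose (median -0.32, adjusted p = 0.00313, median -0.036 under spike-in scaling), and of 10 genes of the RNA exosome (EXOSC) 6 fell and 1 rose (median -0.40, adjusted p = 0.0178, median -0.12 under spike-in scaling), EXOSC9 by 1.05, while EXOSC6 rose by 0.38. Of 48 mitochondrial ribosomal protein genes (MRPL), 28 fell and none rose, with a median of -0.24 (adjusted p = 2e-07), and of 27 MRPS genes 10 fell and none rose, with a median of -0.19. Spike-in scaling, which moves all genes alike by 0.29, turned these medians to 0.046 and 0.10, still below the 0.32 of all genes. Quantile, median and loess scaling kept them negative (MRPL -0.20, -0.30 and -0.21, MRPS -0.15, -0.25 and -0.17). MRPL10 fell by 1.06, the furthest of its family.

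The 5 families that rose, among them kallikreins and Krüppel-like factors, had positive medians under each scaling tried. Of 12 kallikrein genes 6 rose and none fell (median 0.23, adjusted p = 0.0183), KLK10 by 1.82 and KLK11 by 1.45 besides KLK7. Of 15 KLF genes 9 rose and none fell (median 0.35, adjusted p = 0.0429), KLF9 by 1.42 besides KLF4. Of 35 VPS genes, most of them of endosomal and lysosomal sorting, 17 rose and 3 fell (median 0.26, adjusted p = 0.0235), VPS41 by 0.48.

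A trend of fold change with brightness is a candidate technical explanation for the lower MRPL and NUP genes. It was tested first for MRPL and, once that was seen, for NUP, against 10000 random sets of genes matched on mean intensity, and 0% had a median as low as either family. The lowest matched median was -0.21 for MRPL and -0.31 for NUP. This argues against such a trend as the whole cause. Whether the MRPL transcripts fell in absolute amount depends on the scaling. Their place below other genes held under quantile and loess scaling, the only scalings tried that could have changed it. A biological effect of the knockdown on either family remains a hypothesis.

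The histone signals on these arrays did not fall with the DNA replication genes as a group (median 0.12, camera adjusted p = 0.603). Many of them were dim, and whether these arrays read the bulk of histone mRNA was not tested. Among brighter ones, H2AZ1 fell by 0.36 and H2AZ2 by 0.31, whereas H2BC12 rose. Of 35 histone genes 7 rose and 6 fell, H2AC6 by 1.34, H2BC5 by 1.15 and H2BC12 by 1.02 upwards, while H2AX fell by 1.26 and H4C11 by 1.21. Cross-hybridisation between near-identical copies may contribute. Of the 7 raised H1, H2A and H2B genes, 4 were read by probe sets not marked as matching several transcripts, fewer than the 5 set as the minimum for a verdict. These genes were picked because they had risen, so their fold changes could not have come out negative and are no test, and cross-hybridisation and a rise of these transcripts cannot be told apart.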
